A study of Homo sapiens with 12 samples.

How the data were processed

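K562 cells carried a library of dual-sgRNA constructs for CRISPR interference, and the abundance of each construct was read by sequencing. Per the labels, the sgRNA cassettes were amplified by PCR from genomic DNA, and no molecular identifiers were named. The labels name Bowtie2 2.3.4.1 without saying how it was used. The deposited count tables hold raw counts of reads per construct, which the values bear out: they were whole numbers with a different total in each library. Each deposited phenotype table holds log2 values that the authors computed for each replicate, for growth without drug (gamma), growth with drug (tau) and drug response (rho). Those values were recomputed from the counts to within 1e-09: the log2 ratio of end over start with 10 added to each count, minus the median over constructs with 2 non-targeting sgRNAs, divided by a constant. The constants were 7.19 and 7.73 in 2022 and 8.04 and 7.98 in 2023 for gamma, and 5.32, 5.36, 5.4 and 4.98 for tau. They have the size of cell doublings, and they are read so below, although the sources used here do not name them. The phenotype tables left out constructs with 50 reads or fewer in a T0 library and also left out 16 sgRNAs in 2022 and 30 in 2023, so all values below start from the counts.

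Per the labels, each replicate culture was sampled at T0 and then divided into the drug and reference arms. The replicate number therefore pairs the 3 libraries of one culture, and all fits hold that pairing. Groups came from the labels, with 2 libraries in each of 6 groups. As a check, the difference of replicate 1 and replicate 2 in log2 counts was correlated between arms of a screen over 1267355 constructs, which are not independent replicates. Pearson r was 0.0319 to 0.0813, above 0 for all 6 pairs of arms but weak, so the pairing rests on the labels.

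For single genes, counts were summed over the 220 constructs that pair a sgRNA of the gene with a non-targeting sgRNA. Library sizes were the summed counts of the 3025 constructs with 2 non-targeting sgRNAs, so that a log2 value of 0 is the level of the non-targeting controls. The sums ran from 757 reads upward, with a median of 53519. All 12 libraries entered one edgeR 4.0.16 quasi-likelihood fit in R 4.3.3 with a block for each screen and replicate and a term for each arm within each screen. Growth was reference minus T0, and response was niraparib minus reference, each averaged over both screens. The screen difference was 2023 minus 2022. Each non-targeting sgRNA was fitted as if it were a gene, and p-values were adjusted by Benjamini-Hochberg over the 543 genes and 55 non-targeting sgRNAs of each contrast, with a threshold of 0.05. The biological coefficient of variation was 3.06%, with 4 residual degrees of freedom. The error of this fit comes from within the screens, so its SE and p-values leave out the difference between the screens. They do not measure the SD over the 4 replicates printed with single genes, for instance an SE of 0.047 and an SD of 0.34 for CAD in growth. Tested on simulated data, the fit recovered 100% of 50 changes of 0.25 and made 9 false calls among 398 unchanged genes and controls. The simulation gave all genes the same dispersion. In the real response test the SE differed between genes, for instance 0.01 for POLB and 0.18 for BRCA2, so the recovery does not carry over to the more variable genes.

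Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 15 lists with at least 3 measured genes. The lists fixed before the data were examined were PARP1 and ADP-ribose turnover, base excision and single-strand break repair, homologous recombination, the BLM-TOP3A-RMI complex, the BRCA1-A complex, non-homologous end joining, the 53BP1-shieldin axis, Fanconi anemia, fork reversal and fork protection, the ATR-CHK1 checkpoint, mismatch repair, RNase H2, replisome and polymerases, structure-specific nucleases and topoisomerases. Another 5 had fewer than 3 measured genes and were not tested: nucleotide excision repair, translesion synthesis, CTF18 and alternative clamp loaders, drug efflux and a list with CHEK2. A further 21 lists were written after the gene names of the library were seen and before any value was. As no cell type but K562 was present, no cell type markers applied.

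Interaction scores started from constructs with a mean T0 count of at least 30. For each replicate, the log2 ratio of endpoint over T0 with 1 added to each count was set to the median of the constructs with 2 non-targeting sgRNAs and averaged over both orders. For each sgRNA, a curve of degree 2 was fitted through its partners (at least 100) on their own phenotypes, and the residuals were averaged over sgRNA pairs of a gene pair. A score below 0 means a pair was more depleted than this expectation, and a score above 0 means less. The differential score was the niraparib score minus the reference score of the same replicate. The 4 replicate scores of 147044 gene pairs were tested in limma with a term for the screen and a trend on mean log2 count. With 2 residual degrees of freedom, limma borrowed 25.7 to 37.7 prior degrees of freedom across pairs. The SE printed with a score is the moderated one from this fit. It leaves out the difference between the screens and can be far below the spread of the 4 replicates. Tested on simulated data, the fit recovered 16% of scores of 0.25, 88% of 0.5 and 100% of 1. It made 15 false calls among 146846 unchanged pairs. The simulation used additive single effects and the same score for all sgRNA pairs of a gene pair, which the real data need not follow. The screen means of the scores correlated across gene pairs, which are not independent replicates, with a Pearson r of 0.427 for reference growth, 0.502 for niraparib growth and 0.303 for the differential score. Profile similarity was the Pearson correlation of 2 genes' scores over all other partners, and its median over gene pairs of fixed complexes was compared with 100000 relabellings of the genes in a one-sided permutation test.

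The rule for named genes was fixed at the same time: the 12 largest rises and 12 largest falls past the threshold with one sign in all 4 replicates and both sgRNAs, PARP1 and PARP2, and up to 4 members of each fixed list past the threshold, or the 2 largest where none passed. For gene pairs, it took the 12 lowest and 12 highest past the threshold with one sign in all 4 replicates, with at most 3 pairs per gene, in reference growth and in the differential score. It took 5 of each in niraparib growth, and up to 10 of 60 fixed pairs (46 measured) past the threshold for each score. Values of a few genes that the rule names are not reported here, and no others took their place, while counts of genes and list tests include them. Other genes and pairs are named with a statement that they were chosen after their values were seen.

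Alternatives were TMM and median-of-ratios scaling, DESeq2 1.42.0, limma on median construct ratios, constructs with a mean T0 count of at least 30, sgRNA positions and single sgRNAs, each screen alone, no replicate block, each replicate left out, and ranges of the non-targeting controls. For scores they were additive and linear expectations, T0 minimums of 10 and 100, 10 added to each count, medians over sgRNA pairs, one construct order, additive scores with no replicate block and a score from the niraparib over reference ratio. Profiles were also compared by Spearman correlation and in each screen alone. A scaling of the niraparib change to the doublings of the reference arm was added after the data were seen, as was the profile test without the Fanconi core complex. A filter on summed T0 counts under 500 removed 0 genes, so it has no value of its own.

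Of the 543 library symbols, 507 were current, 34 were older synonyms and 2 had no single match. Symbols are given as in the files, with the current one in parentheses at first use. The genome build of the sgRNA positions was not stated, so no coordinates are given. The Python 3.11.15 steps used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.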

Results

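Read counts of dual-sgRNA constructs were measured in K562 cells, a human chronic myelogenous leukemia line, in which CRISPR interference repressed transcription at each sgRNA target. The library paired its sgRNAs with one another in both orders, which made 1301881 constructs. It held 2 sgRNAs for each of 543 genes and 55 non-targeting sgRNAs. Each of 2 screens, 2022 and 2023, had 3 arms with 2 replicates: T0 on day 9 after transduction, a reference endpoint with vehicle, and an endpoint after niraparib, an inhibitor of the DNA damage sensors PARP1 and PARP2. In 2022, cells had 2 µM niraparib for 3 days and were harvested on day 18. In 2023, the dose of 2 µM was raised to 3 µM from day 2, the drug was removed after 4 days, and harvest was on day 19. In megareads, the 2022 libraries held 325.9 and 324.8 at T0, 460.7 and 441.2 in reference and 334.6 and 326.7 under niraparib. The 2023 libraries held 221.9 and 221.8 at T0, 200.2 and 187.2 in reference and 216.5 and 182.6 under niraparib. Median reads per construct ran from 100 to 258, and 0.106% to 0.664% of constructs had none. Within groups, the Pearson r of log2 counts across constructs, which are not independent replicates, was 0.936 to 0.972. The replicate differences were 2.2 to 8.14 times those of counting error as a chi-square per degree of freedom. Reads came from PCR without molecular identifiers, so errors from counts alone cover counting error only. Knockdown of each target was not measured.

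The reference endpoint against T0 asked which knockdowns changed growth without drug. Of 543 genes, 462 passed the edgeR test, 439 lower and 23 higher. CAD, the first enzymes of pyrimidine synthesis, fell most, with a log2 change of -4.09 ± 0.34 (SD, n = 4). NOL6, needed to process ribosomal RNA, stood at -3.21 ± 0.38. HJURP, the chaperone of the centromeric histone, stood at -3.15 ± 0.21, GEMIN2 of the SMN complex at -3.06 ± 0.18 and DCTN3 of dynactin at -3.01 ± 0.28. MCM2 of the replicative helicase fell to -2.93 ± 0.19 and DNMT1, the maintenance DNA methyltransferase, to -2.89 ± 0.16. NOP10 and DKC1, of the H/ACA ribonucleoproteins, fell to -2.73 ± 0.23 and -2.72 ± 0.19. IPO13, an importin, stood at -2.71 ± 0.22, TAF2 of TFIID at -2.68 ± 0.28 and NDNL2 (NSMCE3) of the SMC5-SMC6 complex at -2.66 ± 0.08. These 12 falls had adjusted p from 1.91e-10 to 2.64e-09 in edgeR.

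Rises were smaller. C12orf66 (KICS2), a subunit of a complex that restrains mTORC1, rose by 0.75 ± 0.11 (SD, n = 4). TSC1, which restrains mTORC1, rose by 0.13 ± 0.04. The corepressor subunit GPS2 rose by 0.51 ± 0.09 and CBL, a ubiquitin ligase for tyrosine kinase receptors, by 0.38 ± 0.06. MTF2 and EZH2, of Polycomb complex PRC2, rose by 0.30 ± 0.06 and 0.09 ± 0.01, and PHC1, of PRC1, by 0.06, while BMI1 of PRC1 fell to -0.04 and PHC2 (0.00) and CBX6 (-0.01) did not pass (the last 3 were chosen after their values were seen, and no list of these genes was tested). MYEOV2 (COPS9) of the COP9 signalosome rose by 0.19 ± 0.03, HMGXB3 by 0.18 ± 0.04, the repressor E2F7 by 0.07 ± 0.01 and the decay kinase SMG1 by 0.06 ± 0.02. These 11 rises had adjusted p from 4.79e-10 to 0.00506 in edgeR. PARP1, a target of the drug, fell to -0.75 ± 0.39 (edgeR adjusted p = 0.00265), and PARP2 to -0.03 ± 0.01 (edgeR adjusted p = 0.0437). PARP1 did not pass under TMM (-0.29) or median-of-ratios scaling (-0.36), and PARP2 did not pass with no replicate block (-0.03) and had the opposite sign under TMM (0.43). With the second sgRNA alone, E2F7 (0.05), SMG1 (0.03) and EZH2 (0.01) did not pass, and PHC1 (0.03) did not with second positions alone. The highest single non-targeting sgRNA stood at 0.077 in growth, above E2F7, PHC1 and SMG1. The lowest stood at -0.064, below PARP2 and BMI1.

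No member of a fixed list was higher past the threshold in growth. The list members named here had an SD of 0.00682 to 0.515 over the 4 replicates. In the replisome list, 21 of 24 genes fell, 21 when adjusted over the list alone, among them MCM4 at -1.92, RFC3 at -1.87 and MCM6 at -1.77. In homologous recombination, 20 of 26 fell, 20 when adjusted over the list alone, with BARD1 at -1.33, BRCA2 at -1.31 and DNA2 at -1.19. The ATR-CHK1 checkpoint list had 12 of 13 lower, also 12 when adjusted over the list alone, with RAD9A at -1.83, ATR at -1.63, HUS1 at -1.39 and RAD17 at -0.87. In Fanconi anemia, 14 of 15 fell, 14 when adjusted over the list alone, with WDR48 at -0.67, C19orf40 (FAAP24) at -0.59, FANCB at -0.50 and UBE2T at -0.48. All 3 topoisomerases fell, 3 when adjusted over the list alone: TOP2A at -1.75, TOP1 at -1.55 and TOP3A at -0.17. Base excision and single-strand break repair had 4 of 5 lower, 4 when adjusted over the list alone, with LIG1 at -0.61, XRCC1 at -0.43 and LIG3 at -0.24. All 4 genes of the BLM-TOP3A-RMI complex fell, 4 when adjusted over the list alone, with BLM at -1.12, RMI1 at -0.43 and RMI2 at -0.17. All 3 RNase H2 subunits fell, 3 when adjusted over the list alone: RNASEH2C at -0.88, RNASEH2B at -0.28 and RNASEH2A at -0.21. All 5 genes of the structure-specific nuclease list, which includes the polymerase POLQ, fell, 5 when adjusted over the list alone. Among them were SLX4 at -0.52, GEN1 at -0.34, EME1 at -0.22 and POLQ at -0.06. Under TMM scaling the sign turned for TOP3A (0.28), LIG3 (0.21), XRCC1 (0.02), RMI1 (0.02), RMI2 (0.28), RNASEH2A (0.24), RNASEH2B (0.18), GEN1 (0.11), EME1 (0.24) and POLQ (0.40), and FANCB (-0.04), UBE2T (-0.02) and SLX4 (-0.07) did not pass. With the second sgRNA alone, RMI1 (-0.02), RNASEH2A (-0.03), GEN1 (-0.02) and POLQ (-0.02) did not pass.

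The 53BP1-shieldin axis had 7 of 9 lower, 7 when adjusted over the list alone, with RIF1 at -0.69, DYNLL1 at -0.38, RNF8 at -0.23 and TP53BP1 at -0.20. In non-homologous end joining, 3 of 6 fell, 2 when adjusted over the list alone: XRCC5 at -1.61, XRCC6 at -0.57 and LIG4 at -0.08. In PARP1 and ADP-ribose turnover, 3 of 5 fell, 2 when adjusted over the list alone, and besides PARP1 and PARP2 these included CHD1L at -0.17. Mismatch repair had 2 of 3 lower, 2 when adjusted over the list alone, with MSH6 at -0.49. Fork reversal and protection had 2 of 6 lower, 2 when adjusted over the list alone: CLSPN at -1.44 and WDHD1 at -0.999. In the BRCA1-A complex, 2 of 4 fell, 1 when adjusted over the list alone: BRCC3 at -0.08 and FAM175A (ABRAXAS1) at -0.03. Of the lists too small to test, CHTF18 stood at -0.55, ERCC1 at -0.20 and RAD18 at -0.18, all past the threshold, and the drug efflux pump ABCB1 at 0.00 (edgeR adjusted p = 0.876). Under TMM scaling the sign turned for DYNLL1 (0.08), RNF8 (0.22), TP53BP1 (0.26), LIG4 (0.37), CHD1L (0.28), BRCC3 (0.37), FAM175A (0.42), ERCC1 (0.25) and RAD18 (0.28), CHTF18 (-0.10) did not pass, and ABCB1 (0.46) did. Without 2023 replicate 1, TP53BP1 (-0.18), LIG4 (-0.09), CHD1L (-0.17) and FAM175A (-0.04) did not pass.

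Against the other genes, 0 of the 15 tested lists passed camera in growth, with adjusted p of 0.28 to 0.952 (0.894 to 0.982 with an estimated correlation), and 2 had an unadjusted p under 0.05. Camera compared each list with the other genes, and 10 lists had an upward direction there although their medians lay below 0. The screens gave 448 genes in 2022 and 440 in 2023. Of 55 non-targeting sgRNAs, 3 passed, and 95% of the 55 lay between -0.03 and 0.03 on the log2 scale. The lowest stood at -0.064, and FAM175A, POLQ and PARP2 did not fall below it. Directions in growth are relative to these controls: TMM scaling moved the median of all genes by 0.45 and left 249 higher and 259 lower, and 20 of the named genes with falls from -0.03 to -0.43, PARP2 among them, had positive values there. The PARP1 fall did not pass under TMM or median-of-ratios scaling.

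**Figure D1:**
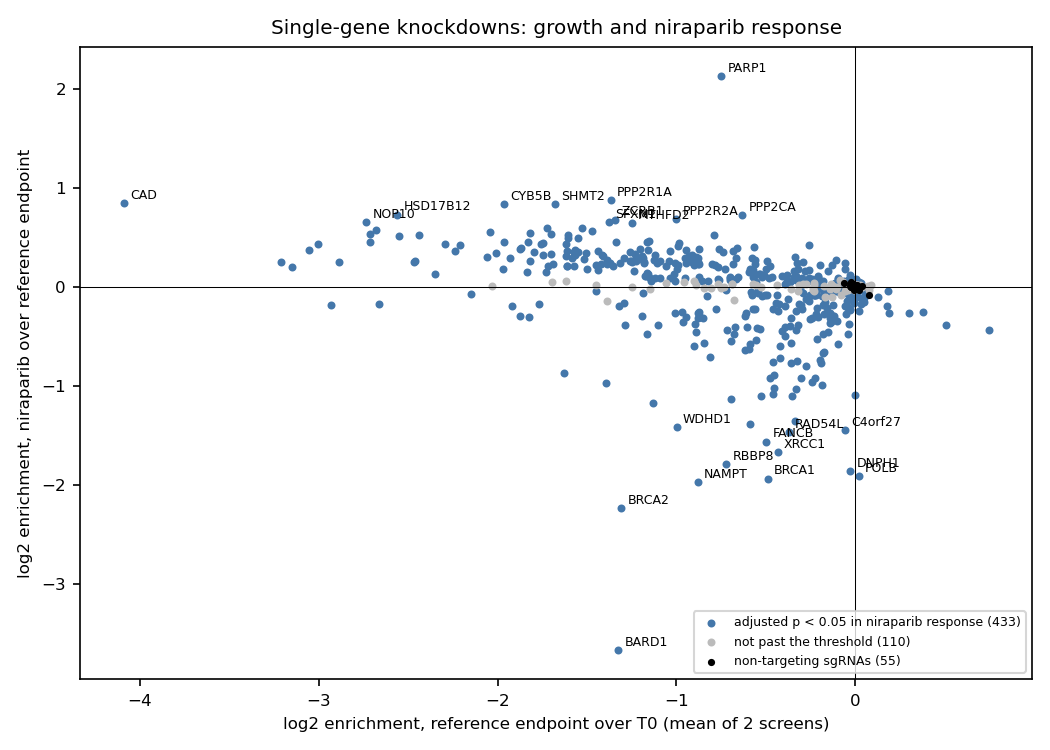
Each point is a gene or a non-targeting sgRNA, with its log2 change in growth without drug on the x axis and its log2 change under niraparib against reference on the y axis, both averaged over the screens. Blue points (433 genes) passed the niraparib test, grey points did not, and black points are the 55 non-targeting sgRNAs; PARP1 stands alone at the top at 2.13, and BARD1 is lowest at -3.67.

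The niraparib endpoint against the reference endpoint asked which knockdowns made cells more sensitive or more resistant to the drug. Of 543 genes, 193 were lower under niraparib and 240 were higher in edgeR. BARD1 and BRCA1, partners in the ubiquitin ligase that directs homologous recombination, fell to -3.67 ± 0.47 and -1.94 ± 0.18 (SD, n = 4). BRCA2, a mediator of strand exchange, fell to -2.23 ± 0.60, RBBP8, which starts end resection, to -1.79 ± 0.24 and RAD54L, a DNA translocase of recombination, to -1.46 ± 0.46. NAMPT, the enzyme of NAD salvage, stood at -1.97 ± 0.11 and DNPH1, which clears damaged nucleotides, at -1.86 ± 0.10. The single-strand break repair factors POLB and XRCC1 fell to -1.91 ± 0.19 and -1.67 ± 0.29. FANCB of the Fanconi core complex stood at -1.56 ± 0.16, C4orf27 (HPF1), the cofactor of PARP1, at -1.44 ± 0.15 and the replisome protein WDHD1 at -1.41 ± 0.36. These 12 falls had adjusted p from 7.65e-10 to 0.000221 in edgeR.

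PARP1 knockdown cells rose most, by 2.13 ± 0.34 (SD, n = 4). Of protein phosphatase 2A, the scaffold PPP2R1A rose by 0.88 ± 0.15, the catalytic subunit PPP2CA by 0.72 ± 0.12 and the regulatory subunit PPP2R2A by 0.68 ± 0.11. The wider list of PP2A and PP4 phosphatases had 3 of 7 genes higher and 2 lower, 5 when adjusted over the list alone, and did not pass (camera adjusted p = 0.606, adjusted p = 0.667 with an estimated correlation). Of mitochondrial serine and one-carbon metabolism, SHMT2 rose by 0.83 ± 0.29, the serine transporter SFXN1 by 0.66 ± 0.21 and MTHFD2 by 0.64 ± 0.17. The wider list of one-carbon and serine metabolism passed camera, but not with an estimated correlation or scaled to equal doublings. CAD rose by 0.84 ± 0.33, CYB5B of the outer mitochondrial membrane by 0.83 ± 0.15, HSD17B12 of fatty acid elongation by 0.73 ± 0.14, ZCRB1 of the minor spliceosome by 0.68 ± 0.07 and NOP10 by 0.66 ± 0.09. These 12 rises had adjusted p from 3.56e-07 to 0.00018 in edgeR. PARP2 rose by 0.09 ± 0.03 (edgeR adjusted p = 0.000285). With the niraparib change scaled to the doublings of the reference arm, a scaling chosen after the data were seen that reads unnamed constants as doublings, 60 genes were higher and 367 lower, and CAD (-0.69), NOP10 (-0.33) and HSD17B12 (-0.13) were lower.

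**Figure D2:**
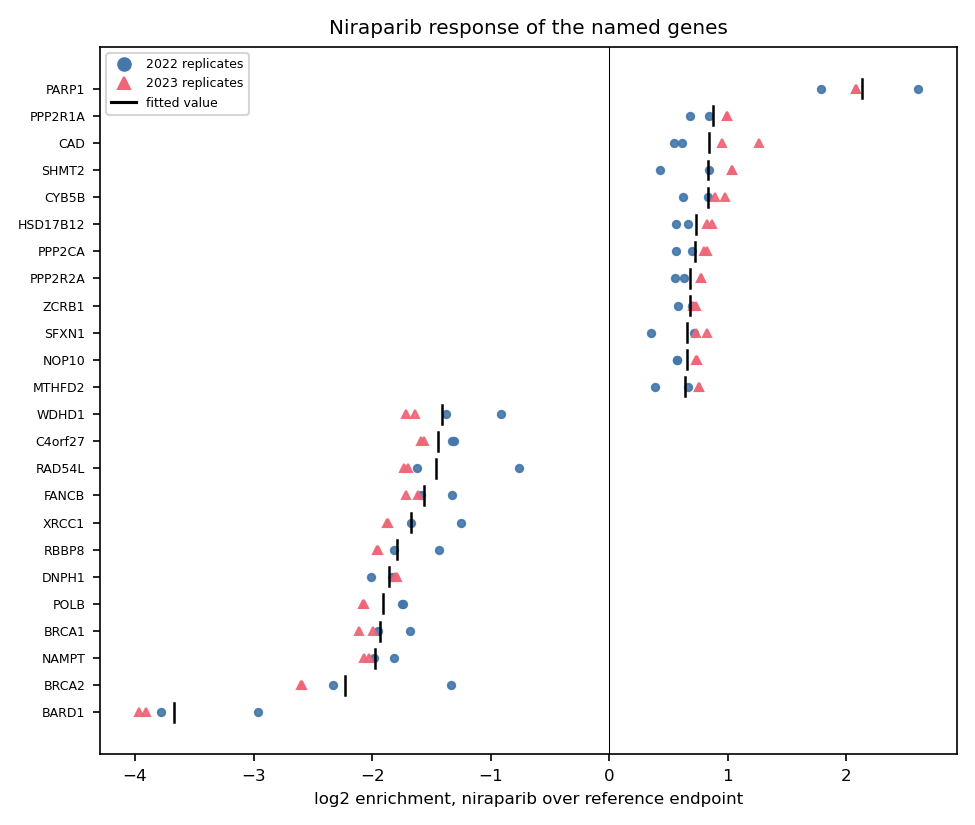
Log2 change under niraparib against reference (x axis) for the 12 largest falls and 12 largest rises, with blue circles for 2022 replicates, red triangles for 2023 replicates and a black bar at the fitted value. BARD1 stands at -3.67, PARP1 at 2.13, and all 4 replicates of each gene lie on one side of 0.

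Among the lists, every one of the 15 Fanconi anemia genes fell, 15 when adjusted over the list alone (camera adjusted p = 4.54e-07, adjusted p = 0.567 with an estimated correlation). After FANCB the lowest were C19orf40 at -1.38, FANCA at -1.36 and FANCD2 at -1.11. Homologous recombination had 22 of 26 genes lower and 4 not past the threshold, 23 when adjusted over the list alone (camera adjusted p = 1.61e-06, adjusted p = 0.567 with an estimated correlation). All 5 genes of base excision and single-strand break repair fell, 5 when adjusted over the list alone (camera adjusted p = 0.00075, adjusted p = 0.567 with an estimated correlation). Besides POLB and XRCC1 these included LIG3 at -0.96, the ligase that partners XRCC1. In the replisome list, 14 of 24 genes were lower, 1 higher and 9 not past the threshold, 14 when adjusted over the list alone (camera adjusted p = 0.0122, adjusted p = 0.585 with an estimated correlation). The clamp loader gave its 4 lowest values: RFC1 at -1.08, RFC4 at -0.71, RFC5 at -0.60 and RFC2 at -0.35. Of 13 ATR-CHK1 checkpoint genes, 10 were lower, 1 higher and 2 not past the threshold, 11 when adjusted over the list alone (camera adjusted p = 0.0209, adjusted p = 0.585 with an estimated correlation). Its lowest were the kinase ATR at -0.87, its activator TOPBP1 at -0.56, its partner ATRIP at -0.44 and the clamp subunit RAD9A at -0.31, which did not pass without 2023 replicate 1 (-0.32). Named members had an SD of 0.00733 to 0.598 over the 4 replicates.

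The other 10 lists did not pass camera, with adjusted p of 0.155 to 0.895. Of the 5 genes in the structure-specific nuclease list, 3 fell and 1 rose, 5 when adjusted over the list alone (camera adjusted p = 0.155). SLX4 stood at -1.10, MUS81 at -0.38, EME1 at -0.28 and GEN1 at 0.10. All 3 RNase H2 subunits fell, 3 when adjusted over the list alone (camera adjusted p = 0.155): RNASEH2C at -0.31, RNASEH2B at -0.12 and RNASEH2A at -0.03. All 4 BRCA1-A genes fell, 4 when adjusted over the list alone (camera adjusted p = 0.155): FAM175A at -0.12, UIMC1 at -0.11, BRCC3 at -0.07 and BABAM1 at -0.05. TOP1 at 0.49 and TOP2A at 0.44 rose and TOP3A at -0.04 fell, 3 when adjusted over the list alone (camera adjusted p = 0.332). In non-homologous end joining, XRCC5 at 0.21 and XRCC6 at 0.17 rose and 4 genes did not pass, 2 when adjusted over the list alone (camera adjusted p = 0.483). The 53BP1-shieldin axis had 3 of 9 genes higher and 4 lower, 7 when adjusted over the list alone (camera adjusted p = 0.703), with RIF1 at -0.55, TP53BP1 at 0.22 ± 0.22, DYNLL1 at -0.12 and RNF8 at -0.09. Its median was 0.01 and its mean -0.04, with a downward test. Fork reversal and protection had 2 higher and 2 lower of 6, 4 when adjusted over the list alone (camera adjusted p = 0.703), with WDHD1 lowest, CLSPN at 0.17, SMARCAL1 at -0.10 and ZRANB3 at 0.06. Its median was 0.01 and its mean -0.21, with a downward test. Scaled to the doublings of the reference arm, rises turned negative for XRCC5 (-0.47), CLSPN (-0.44), TOP2A (-0.18), XRCC6 (-0.03), TOP1 (-0.01) and GEN1 (-0.01). Without 2023 replicate 1, TP53BP1 (0.22), RNF8 (-0.09), RNASEH2A (-0.04), TOP3A (-0.05) and ZRANB3 (0.07) did not pass. With median-of-ratios scaling RNASEH2A and TOP3A were 0.01 and BRCC3 (-0.02) did not pass, and BABAM1 was 0.01 with the first sgRNA alone.

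Mismatch repair had 1 of 3 genes higher and 2 lower, with MSH6 at -0.08, 3 when adjusted over the list alone (camera adjusted p = 0.703). The BLM-TOP3A-RMI complex had BLM higher at 0.09 and RMI1 lower at -0.08, besides TOP3A, 3 when adjusted over the list alone (camera adjusted p = 0.797). MSH6 and RMI1 did not fall below the lowest non-targeting sgRNA (-0.086). In PARP1 and ADP-ribose turnover, 3 genes rose and 1 fell, 5 when adjusted over the list alone (camera adjusted p = 0.895), with PARG, which removes poly(ADP-ribose), at 0.07. Of the lists too small to test, RAD18, a ubiquitin ligase for PCNA, stood at -0.48, CHTF18 at -0.42 and ERCC1 at 0.07, all past the threshold. CHEK2 at 0.00 and ABCB1 at 0.01 did not pass, with edgeR adjusted p of 0.883 and 0.607. None of the 5 list calls held with an estimated correlation, the replisome call was lost without 2022 replicate 1 (camera adjusted p = 0.079) or 2022 replicate 2 (camera adjusted p = 0.12), and the ATR-CHK1 checkpoint call without 2022 replicate 2 (camera adjusted p = 0.13) or scaled to equal doublings (camera adjusted p = 0.1). Scaled to those doublings, BLM (-0.40) turned negative. With single sgRNAs, MSH6 (0.03) and RMI1 (0.02) turned positive and PARG (0.01) and ERCC1 (0.04) did not pass.

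**Figure D3:**
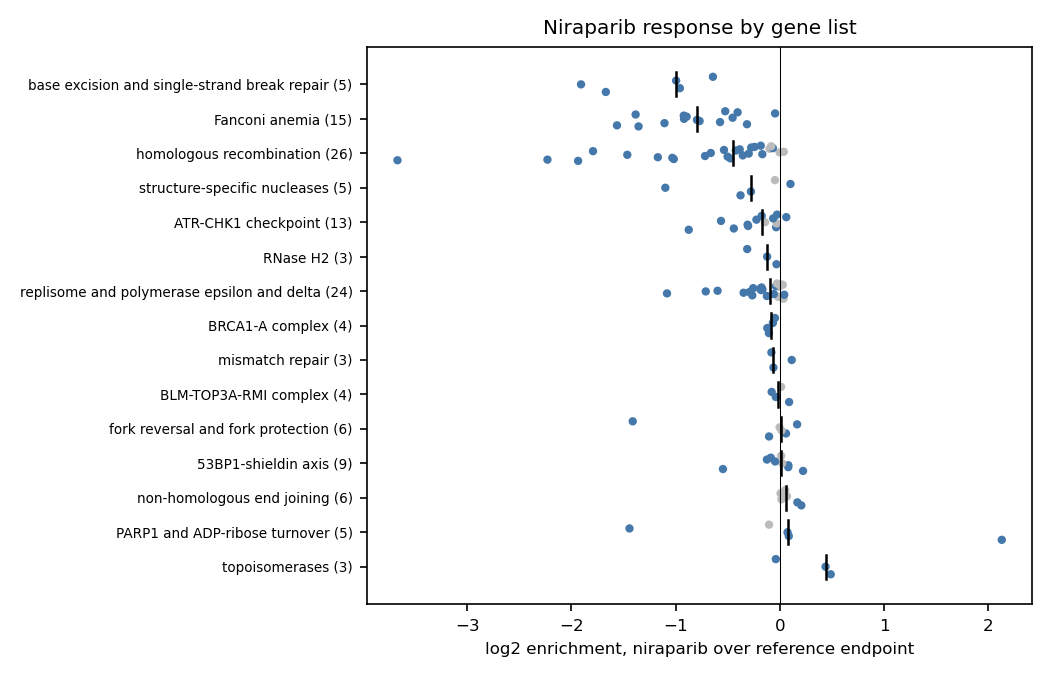
Log2 change under niraparib against reference (x axis) of the measured members of 15 gene lists, with a bar at each list's median and the number of genes in parentheses. Blue points passed the edgeR test and grey points did not; base excision and single-strand break repair (median -0.996) and Fanconi anemia (median -0.80) had the lowest medians.

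Within single screens, 401 genes passed in 2022 and 408 in 2023, and 2 of 55 non-targeting sgRNAs passed in the joint contrast. Whether the response differed between the screens was asked next, since dose and exposure differed. POLB fell further in 2023 (-2.07) than in 2022 (-1.75), a difference of -0.33 (edgeR adjusted p = 0.00216). LIG1, which seals nicks in replication and repair, differed by -0.21, from -0.54 to -0.75 (edgeR adjusted p = 0.0296). These were the only 2 genes past the threshold in edgeR, with 100 at an unadjusted p under 0.05 and 66 past the threshold in DESeq2. As lists, base excision and single-strand break repair (camera adjusted p = 1.74e-06), homologous recombination (camera adjusted p = 0.000225), the replisome (camera adjusted p = 0.000719) and Fanconi anemia (camera adjusted p = 0.00171) were lower in 2023, each with adjusted p = 0.724 with an estimated correlation. Adjusted over the list alone, 5 genes of base excision and single-strand break repair passed and 0 of the other 3 lists. The other 11 lists had camera adjusted p of 0.355 to 0.962, with the ATR-CHK1 list upward in the test at a median of -0.08. The count of 2 was 132 without 2022 replicate 1, 282 without 2022 replicate 2 and 0 without either 2023 replicate, where POLB stood at -0.33 and -0.32 and LIG1 at -0.20 and -0.23. Dose, days in drug, harvest day, DNA extraction, sequencing depth and cells per construct at transduction (350 in 2022, 400 in 2023) changed together between the screens. These cannot be told apart.

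Interaction scores in reference growth asked which pairs of knockdowns grew worse or better together than their single effects gave. BARD1 was most depleted with genes of the Fanconi core complex and its E2 enzyme. BARD1-FANCB scored -2.00 ± 0.10 (moderated SE, n = 4), BARD1-UBE2T -1.84 ± 0.11 and BARD1-FANCA -1.79 ± 0.08. BRCA2 was depleted with HUS1 of the checkpoint clamp (-1.38 ± 0.09), with LIG1 (-1.18 ± 0.10), with PARP1 (-1.13 ± 0.06) and with the end-joining polymerase POLQ (-1.11 ± 0.08). MND1, a recombination cofactor, scored -1.37 ± 0.07 with RAD54L. HUS1 scored -1.19 ± 0.07 with ETAA1, an ATR activator, and CHTF18 scored -1.18 ± 0.08 with CUL2, a cullin. Subunits of the BCDX2 recombination complex were depleted with one another: RAD51B-RAD51D at -1.17 ± 0.06, RAD51B-RAD51C at -1.02 ± 0.10 and RAD51D-XRCC2 at -0.69 ± 0.05. RNASEH2C scored -0.66 ± 0.05 with RNASEH2B and -0.55 ± 0.05 with RNASEH2A, and PARP1 scored -0.65 ± 0.04 with PARP2 and -0.48 ± 0.05 with PALB2. BRCA1 scored -0.62 ± 0.07 with FANCM and -0.55 ± 0.05 with RIF1. PALB2-PARP1 (-0.24) did not pass with an additive expectation and no replicate block. Over the 4 replicates, the SD was 0.40 for BRCA2-HUS1 and 0.40 for ETAA1-HUS1.

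On the positive side, CENPM scored 1.10 ± 0.10 with HJURP (both act at centromeres), HSD17B12 1.10 ± 0.05 with EMC2 of the membrane insertion complex, IPO13 1.05 ± 0.17 with its cargo MAGOH, and CYB5B 1.01 ± 0.04 with the translation factor DENR. These 4 and all negative pairs above rested on 4 sgRNA pairs, and limma adjusted p ran from 6.58e-19 to 3.97e-05. IPO13-MAGOH nonetheless had only 41.1 T0 reads and 29.8 reference reads per construct. For CYB5B-DENR, the SD over the 4 replicates was 0.40. The other 10 of the 24 named pairs rested on 1 or 2 sgRNA pairs with 30 to 50.5 T0 reads per construct. Of these, KPNB1-NOL6 (1.30), EWSR1-NOL6 (1.25), HJURP-PLK1 (1.14), NUP62-PSMB5 (1.10), CAD-RBM8A (1.02), MCM2-NUP62 (1.02), FAM35A (SHLD2)-NOL6 (1.02) and ATXN10-NUP62 (0.99) were positive, and EIF4G1-RCC1 (-1.26) and GTF2B-HAUS1 (-1.22) negative. With a T0 minimum of 10, NUP62-PSMB5 (-0.18) and EIF4G1-RCC1 (0.03) turned, as did GTF2B-HAUS1 (0.12) with an additive expectation. CAD-RBM8A (0.65), EWSR1-NOL6 (0.53) and FAM35A-NOL6 (0.03) did not pass with that minimum, nor ATXN10-NUP62 (0.83) in 2022 alone.

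In all, 13158 of 147044 gene pairs passed in limma, 6357 negative and 6801 positive, and 12252 had one sign in all 4 replicates. An absolute score of at least 0.5 was held by 816. Of 46 fixed pairs, 20 were negative and 1 positive. Genes in most negative pairs were C16orf59 (TEDC2) with 160, HUS1 with 151 and DNMT1 with 136, and in most positive pairs C12orf66 with 213. The hub genes were chosen after their counts were seen. As a control, each of 27 pseudo-genes of 2 non-targeting sgRNAs was paired with the library genes. Of 14656 such pseudo-pairs, 0 passed in limma, with 1219 at an unadjusted p under 0.05. The expectation was fitted on these same constructs, which holds their scores near 0 in part by construction, so this control is not independent. The count rested on the expectation and the libraries: it was 67178 with an additive expectation (3821 negative and 63357 positive, 8495 of them shared and with the same sign), 3264 in 2022 alone, 7406 in 2023 alone, 5444 without 2022 replicate 1 and 5750 without 2022 replicate 2. It was 6463 with a further bound at the 99th percentile of the controls.

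The differential score, niraparib minus reference growth, asked which interactions changed with the drug. PARP1 stood in 288 positive pairs and 13 negative ones, and BRCA2 came next with 79 positive pairs (chosen after their counts were seen). With a score from the niraparib over reference ratio, PARP1 stood in 210 positive and 21 negative pairs and BRCA2 in 24 and 45, and 2613 of the 4908 calls were shared with one sign. PARP1 knockdown scored 3.08 ± 0.08 (moderated SE, n = 4) with BARD1, 2.66 ± 0.05 with XRCC1 and 2.59 ± 0.05 with NAMPT. With POLB it scored 2.49 ± 0.03 and with BRCA1 2.24 ± 0.05. It scored 1.81 ± 0.11 with BRCA2, 1.49 ± 0.06 with PALB2, 1.21 ± 0.04 with LIG3 and 1.00 ± 0.04 with C4orf27. Each of those partners alone was lower under niraparib. The sign of named PARP1 pairs depended on the scoring: with that ratio score, NAMPT-PARP1 was -0.14, BRCA1-PARP1 -0.03, BRCA2-PARP1 -0.58, PALB2-PARP1 -0.31, LIG3-PARP1 -0.29 and C4orf27-PARP1 -0.81. PARP1-POLB (0.12) did not pass there, while BARD1-PARP1 (0.64) and PARP1-XRCC1 (0.29) stayed positive and past the threshold.

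TP53BP1, which limits end resection, scored 1.57 ± 0.08 with BARD1, 1.23 ± 0.06 with FANCB and 0.83 ± 0.05 with BRCA1. LIG1 scored 1.42 ± 0.15 with NAMPT and 1.35 ± 0.12 with XRCC1. BRCA2 scored 1.29 ± 0.20 with KIAA1524 (CIP2A), which holds broken chromosomes in mitosis, 1.14 ± 0.18 with HUS1, 1.13 ± 0.16 with TOPBP1 and 1.00 ± 0.17 with POLQ. BARD1-FANCB, the lowest pair in reference growth, scored 1.71 ± 0.26, but with 8.09 niraparib reads per construct, from 160 at T0, a further loss could be hidden. Among named pairs on 4 sgRNA pairs, the most negative held AUNIP, a promoter of end resection: -1.67 ± 0.12 with UBE2T, -1.38 ± 0.06 with RAD18 and -1.32 ± 0.10 with FANCD2. The nuclease partners EME1 and MUS81 scored -1.02 ± 0.05, RNASEH2B-RNASEH2C -0.41 ± 0.08 and BRCA2-C19orf40 -0.98 ± 0.14, the last of which was 0.51 with an additive expectation. ZAR1L scored -0.98 ± 0.11 with SWI5 and -0.96 ± 0.08 with MND1, both of which serve recombination, and the nearest ZAR1L and BRCA2 sgRNA targets lay 123 bp apart. These pairs rested on 4 sgRNA pairs, with limma adjusted p from 9.76e-29 to 0.000906. A further 6 rested on 1 or 2 sgRNA pairs with 31.8 to 47.2 T0 reads per construct: NOL6-UTP14A (-1.51), ALG1-NOL6 (-1.35), PARG-PLK1 (-1.22), CAD-RBM8A (-1.22), COPS3-NOL6 (-1.20) and FANCM-NUP62 (1.26). With a T0 minimum of 10, PARG-PLK1 was 0.11, and ALG1-NOL6 (-0.22), CAD-RBM8A (-0.62), COPS3-NOL6 (-0.62) and NOL6-UTP14A (-0.78) did not pass. With the ratio score, CAD-RBM8A (-0.88), COPS3-NOL6 (-1.09) and NOL6-UTP14A (-1.43) did not pass. In 2022 alone, BRCA2-KIAA1524 (1.08), BRCA2-POLQ (0.73) and FANCM-NUP62 (0.78) did not pass, and in 2023 alone RNASEH2B-RNASEH2C (-0.36) did not.

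**Figure D4:**
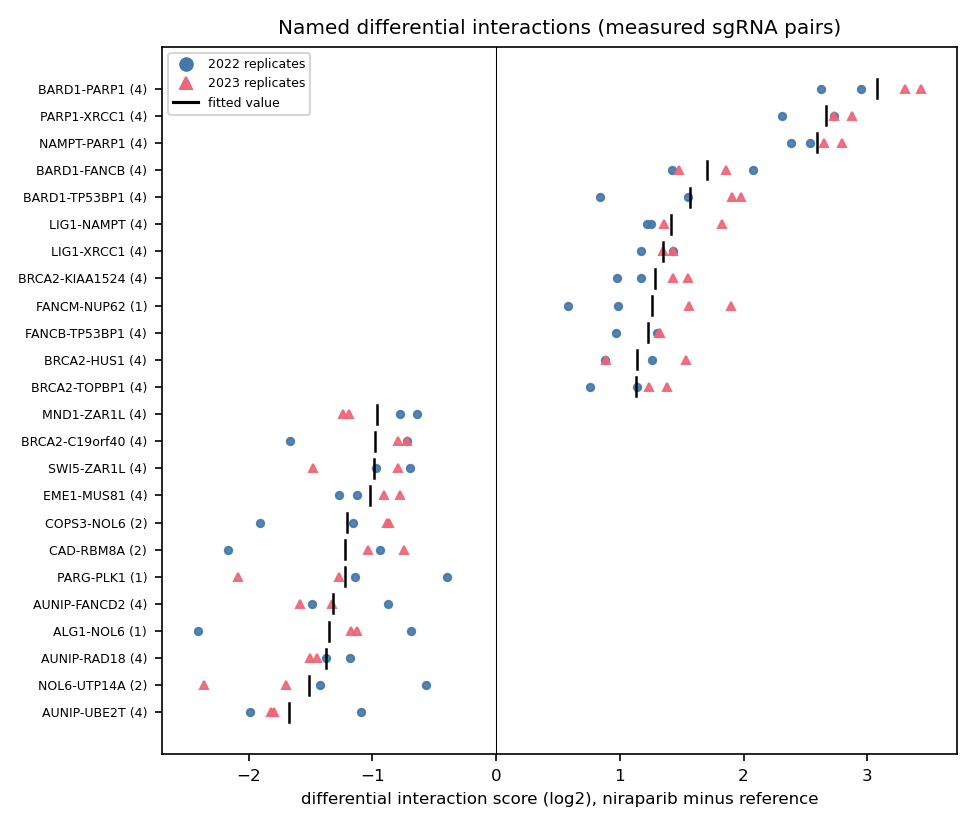
Differential interaction score in log2 units (x axis) of the 24 named gene pairs, with blue circles for 2022 replicates, red triangles for 2023 replicates, a black bar at the fitted value and the number of measured sgRNA pairs in parentheses. BARD1-PARP1 is highest at 3.08 and AUNIP-UBE2T lowest at -1.67.

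Across all pairs, 4908 passed in limma, 2947 negative and 1961 positive, 4704 with one sign in all 4 replicates and 826 with an absolute score of at least 0.5. Of the 46 fixed pairs, 5 were negative and 13 positive. Negative pairs held DNPH1 131 times, POLB 125, AUNIP 121, C4orf27 112 and LIG3 105 times, all chosen after their counts were seen. With the ratio score, the counts were 153 for DNPH1, 123 for POLB, 77 for AUNIP, 91 for C4orf27 and 62 for LIG3. Among the non-targeting pseudo-pairs, 0 passed in limma, with 876 at an unadjusted p under 0.05. With an additive expectation the count was 27405 and most were positive (9894 negative and 17511 positive, 2803 of them shared and with the same sign). It was 1516 in 2022 alone, 2879 in 2023 alone, 3240 without 2022 replicate 1, 2749 without 2022 replicate 2 and 7377 without 2023 replicate 1. In one construct order it was 2145 and in the other 2172, and 3227 with the bound from the controls.

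Scores in niraparib growth asked which pairs deviated in the presence of the drug. The highest were PARP1-XRCC1 at 2.75 ± 0.03 (moderated SE, n = 4), NAMPT-PARP1 at 2.64 ± 0.04, BARD1-PARP1 at 2.45 ± 0.05 and BARD1-TP53BP1 at 2.42 ± 0.06. Of the fixed pairs, PARP1-POLB scored 2.40 ± 0.03, BRCA1-PARP1 1.93 ± 0.04, BRCA1-TP53BP1 1.29 ± 0.05, LIG3-PARP1 1.10 ± 0.03, PALB2-PARP1 1.01 ± 0.04 and C4orf27-PARP1 0.92 ± 0.04. Among named pairs on 4 sgRNA pairs, AUNIP gave the lowest scores, with UBE2T (-1.99 ± 0.12), FANCD2 (-1.64 ± 0.10) and C19orf40 (-1.57 ± 0.09). RNASEH2C scored -1.07 ± 0.06 with RNASEH2B and -0.84 ± 0.06 with RNASEH2A, and RAD51D-XRCC2 scored -0.82 ± 0.06. All of these rested on 4 sgRNA pairs, with limma adjusted p from 2.25e-43 to 1.18e-12. MAPKAP1-NOL6 (-1.86 ± 0.59), HAUS1-PRKDC (-1.48 ± 0.41) and NOL6-PPP2R2A (1.32 ± 0.33) rested on 1 sgRNA pair each and did not pass with a T0 minimum of 10 (-0.44, -0.41 and 0.23). In limma, 18332 pairs passed, 8871 negative and 9461 positive, with 15 negative and 11 positive among the fixed pairs, and 1 pseudo-pair passed. The count was 74639 with an additive expectation (4617 negative and 70022 positive, 12089 of them shared and with the same sign), 6443 in 2022 alone, 10488 in 2023 alone, 9222 without 2022 replicate 1 and 9553 without 2022 replicate 2. It was 11360 and 11980 in single construct orders and 8509 with the bound from the controls.

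Profile similarity asked whether subunits of one complex had like interactions across the other genes. Over 115 gene pairs in 24 complexes fixed beforehand, the median Pearson r was 0.405 in reference growth, 0.641 in niraparib growth and 0.561 for the differential score. Random relabellings gave medians of 0.0552, 0.0516 and 0.0355 and highest values of 0.219, 0.233 and 0.144 (permutation p = 1e-05 for each, the smallest that 100000 relabellings can give). FANCA-FANCB of the Fanconi core reached 0.784 in reference growth and 0.816 in the differential score, RAD51D-XRCC2 0.798 and 0.68, and BARD1-BRCA1 0.782 and 0.613. Some partners had opposite profiles in the differential score: PARP1 and its cofactor C4orf27 at -0.69 and RIF1-TP53BP1 at -0.358. In end joining, the signs were mixed in reference growth. NHEJ1-XRCC4 stood at -0.264, LIG4-XRCC4 at -0.0782, PRKDC-XRCC5 at -0.0731 and PRKDC-XRCC6 at -0.05, but LIG4-NHEJ1 at 0.299 and XRCC5-XRCC6 at 0.0999. Examples were chosen after their values were seen. The Fanconi core gave 55 of the 115 pairs, and without it the medians were 0.305, 0.457 and 0.37 (permutation p = 1e-05 each). With an additive expectation, the reference growth median was 0.681 against a random median of 0.548 and did not pass (permutation p = 0.106).

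**Figure D5:**
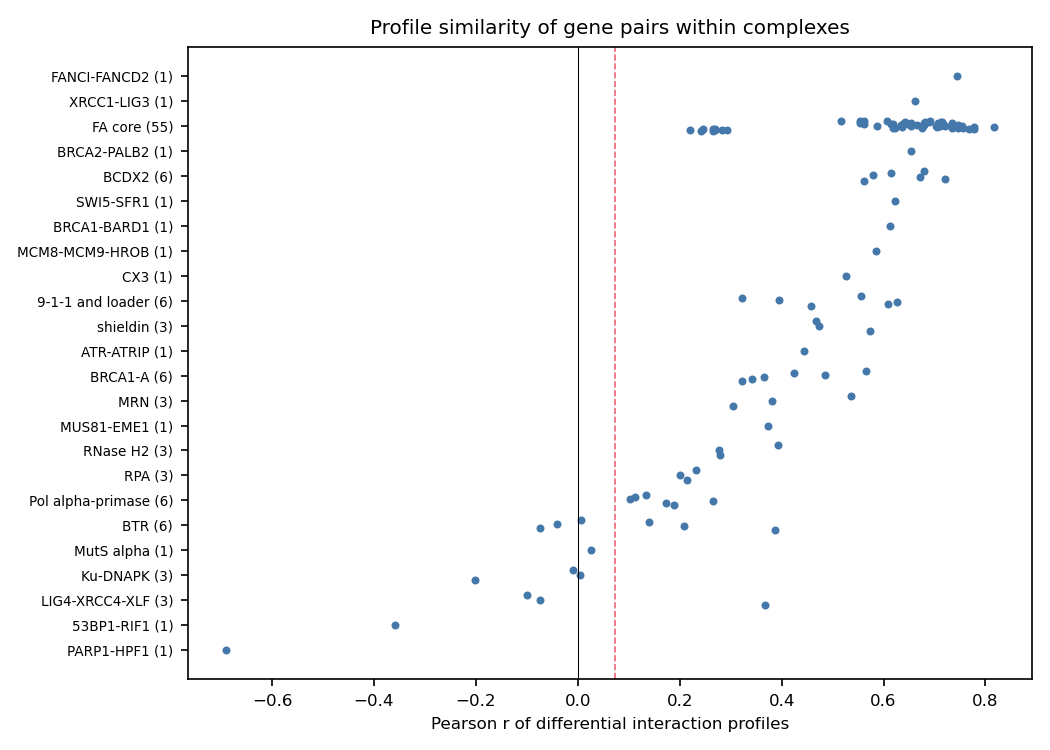
Pearson r of differential interaction profiles (x axis) for gene pairs within each of 24 complexes, with the number of pairs in parentheses. The dashed red line (0.0722) bounds from above the central 95% of median r over random relabellings. It applies to the median over all 115 pairs and is no bound for a single pair or complex. By the median of each complex, FANCI-FANCD2 (0.745) and XRCC1-LIG3 (0.661) lie highest and PARP1-HPF1 lowest at -0.69.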

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

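Tests of the doubling and low-count explanations for rises under niraparib, and of pairs picked on the 2022 reference score alone, were chosen after the result was seen; the others were set before. Groups held 2 libraries, too few to test single libraries as outliers. The next 2 paragraphs hold results that differed between the screens in a test of the difference itself.

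In reference growth, 168 of 543 genes differed between the screens in edgeR, 162 with a lower value in 2023. The constants read as doublings were 7.19 and 7.73 in 2022 and 8.04 and 7.98 in 2023, and harvest day and DNA extraction differed too. Named genes differed, as log2 change in 2023 minus 2022, by -0.64 for NOL6, -0.57 for CAD, -0.48 for DCTN3, -0.48 for TAF2, -0.39 for NOP10, -0.37 for IPO13, -0.35 for HJURP and -0.32 for MCM2. The difference was -0.31 for DKC1, -0.30 for XRCC5, -0.29 for GEMIN2, -0.29 for RFC3, -0.24 for DNMT1, -0.20 for DNA2, -0.18 for MCM6, -0.18 for TOP1, -0.16 for BLM, -0.16 for XRCC6, -0.11 for WDR48 and -0.07 for ERCC1. Genes with a rise rose further in 2023, by 0.19 for C12orf66, 0.14 for GPS2, 0.07 for TSC1 and 0.06 for HMGXB3. In the niraparib response, POLB differed by -0.33 and LIG1 by -0.21.

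Among gene pairs, limma found a screen difference for 7 scores. PARP1-POLB differed by 0.46 in the differential score (2.26 in 2022, 2.72 in 2023) and by 0.42 in niraparib growth. CYB5B-DENR differed by 0.68 in reference growth (0.67 to 1.35), and MED23-PTPN1 by 0.39 (0.30 to 0.69) and CDK4-XRCC6 by 1.29 (-0.86 to 0.44) in niraparib growth, each on 4 sgRNA pairs. PLK1-TOP3A differed by 2.41 in reference growth (-0.85 to 1.56) and COPE-HAUS1 by -4.23 in niraparib growth (1.17 to -3.06), each on 1 sgRNA pair.

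The 240 genes higher under niraparib than in reference had a median growth of -0.99 and a median response of 0.235 in log2 units. Fewer cell doublings in the niraparib arm may account for part of this and stay open: scaled to the doublings of the reference arm, their median was -0.0855, with 55 still higher and 135 lower, but the scaling lowers depleted genes whatever the cause (median of all genes -0.196), so it does not decide. For PARP1 and the phosphatase subunits PPP2CA, PPP2R1A and PPP2R2A the tables argue against it, since the lowest of the 4 scaled values was 0.537 and all stayed past the threshold. Low summed counts were checked with a bound set after the data were seen. The lowest endpoint sum of these genes was 757 reads, which was also the lowest of any gene in any library. No gene of the library could have failed that check, so it shows only that the sums held at least that many reads. The scaling rests on reading the constants of the authors' tables as doublings, and no biological explanation was tested.

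Library genes whose sgRNA targets lay within 5000 bp of those of another gene had like profiles: over 11 such pairs the median r of differential profiles was 0.303, against a random median of 0.0362 and an upper bound of 0.128 for the central 95% (one-sided permutation p = 1e-05, the smallest possible). This is consistent with sgRNAs of one gene also repressing its neighbour, for instance ZAR1L (response -0.92) 123 bp from BRCA2, DCTN5 (-1.13) 187 bp from PALB2 and MOSPD2 (-0.28) 424 bp from FANCB. AURKA-CSTF1 (0.0525), only 494 bp apart, ATP6V1A-NAA50 (0.0503) and MCM4-PRKDC (-0.0996) did not have it. Shared function of neighbours stays open, and transcript levels were not measured. No biological explanation was tested.

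Of 470 pairs past the threshold at a reference growth score of -0.5 or lower, 96 had a positive differential score past the threshold and 8 a negative one. Selection on reference scores, which enter the difference with the opposite sign, was checked with 409 pairs picked on the 2022 reference score alone. Errors of the 2022 libraries do not enter the 2023 difference. What both screens share in the reference score (Pearson r of screen means 0.427) does enter it. The relabelled pairs were not picked on a reference score, so only selection on 2022 errors is argued against as the whole cause. The 409 pairs had a median 2023 differential score of 0.115 (0.226 in 2022). This was above the highest of 10000 relabellings of the genes (0.0375). It was under the 99th percentile of single control pairs (0.2552), a bound first used that does not apply to a median. In 2023, 34 of the 409 pairs were positive and 17 negative past the threshold. The 23 that also had a positive 2022 differential score past the threshold were all above 0 in 2023 (median 0.999), but these were picked for the pattern and decide nothing. A floor of reads could also hide a further loss under niraparib: the 96 pairs had a median of 43.9 niraparib reads per construct, from 207 at T0 and 88.8 in reference, between the bounds set beforehand (under 10, or 50 and more), and 7 had under 10. Fewer cell doublings in the niraparib arm could shrink a score as well. Scaled to equal doublings, 6202 pairs passed in the differential score in limma, 3626 negative and 2576 positive. Of the named pairs in that score, 31 counted as unchanged there and 2 kept the direction but no longer passed. The 96 pairs as a set were not followed there. Selection on what the screens share, a floor, fewer doublings and a weaker interaction under the drug were not told apart here, and no biological explanation was tested.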

How the results depend on the processing

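The scaling to equal doublings and the profile test without the Fanconi core complex were chosen after the data were seen; the other alternatives were set before. Of the alternatives run for named results, 2191 gene values, 1285 pair values and 31 list values counted as unchanged. These kept their direction and side of the threshold, or passed in neither setting whatever their sign. A further 103, 94 and 9 kept the direction but no longer passed, and 4 gene values passed only there. Sign changes with a pass in at least 1 of the settings numbered 55 for genes and 13 for pairs. Counts of single genes stayed between 424 and 509 in growth (462) and between 378 and 474 in response (433) over all alternatives run. Depth limits pairs: 437 rested on 1 sgRNA pair, and scores of 0.25 were recovered in 16% of simulated cases. Where a replicate was left out, the lone library of an arm was assumed to vary like the others. The cause of the changes below was not tested, unless stated.

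Without the replicate block, growth had 465 genes, response 438 and the screen difference 2, and the lists 0, 5 and 4; PARP2 growth no longer passed there, and no other named gene or list changed its call. Paired and unpaired scores were compared with an additive expectation: it gave 67178 pairs in reference growth (3821 negative, 63357 positive), 27405 in the differential score (9894, 17511) and 74639 in niraparib growth (4617, 70022), a balance unlike that of the quadratic expectation, and 59214, 33525 and 72725 with no replicate block. Under it, GTF2B-HAUS1 was 0.12 and BRCA2-C19orf40 0.51 (0.12 and 0.53 with no replicate block), and the complex profile median in reference growth was 0.681 and no longer passed.

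TMM moved the median of all genes in growth by 0.45 and median-of-ratios scaling by 0.39, which by construction centre genes that mostly fell: 249 were higher and 259 lower under TMM, 236 and 273 under median-of-ratios, against 23 and 439, and 282 and 296 were shared with one sign. Under TMM all 55 non-targeting sgRNAs passed in growth, and 4 in response (4 in DESeq2), against 3 and 2. In response, median-of-ratios scaling gave 302 higher and 157 lower. Growth values with the opposite sign, under TMM and then median-of-ratios, were BRCC3 0.37, 0.31, CHD1L 0.28, 0.22, DYNLL1 0.08, 0.01, EME1 0.24, 0.17, ERCC1 0.25, 0.19, FAM175A 0.42, 0.36, GEN1 0.11, 0.05, LIG3 0.21, 0.15, LIG4 0.37, 0.31 and PARP2 0.43, 0.36. They were also POLQ 0.4, 0.33, RAD18 0.28, 0.21, RMI2 0.28, 0.22, RNASEH2A 0.24, 0.18, RNASEH2B 0.18, 0.11, RNF8 0.22, 0.16, TOP3A 0.28, 0.22, TP53BP1 0.26, 0.19 and, under TMM alone, RMI1 0.02 and XRCC1 0.02. In response, RNASEH2A and TOP3A were 0.01 under median-of-ratios.

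Scaled to equal doublings, response values turned for BLM (-0.4), CAD (-0.69), CLSPN (-0.44), GEN1 (-0.01), HSD17B12 (-0.13), NOP10 (-0.33), TOP1 (-0.01), TOP2A (-0.18), XRCC5 (-0.47) and XRCC6 (-0.03), with 60 genes higher and 367 lower. In single sgRNAs, BABAM1 was 0.01 and MSH6 0.03 with the first and RMI1 0.02 and RNASEH2A 0.01 with the second. CHEK2 was -0.01 without 2022 replicate 2 and did not pass in the joint contrast. The screen difference in response (2 genes) had 66 in DESeq2, 1 with second positions, 1 and 6 with first and second sgRNAs, 224 scaled to equal doublings and 0 to 282 with replicates left out (edgeR, 22 and 18 at an unadjusted p under 0.05 where it was 0). With an estimated correlation, 0 lists passed in response (5) and 0 in the screen difference (4), and leaving out replicates gave 3 to 5 in response.

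Pairs in reference growth (13158) numbered 3264 in 2022 alone, 7406 in 2023 alone, 6463 with the bound from controls and 5444 to 16723 with replicates left out. The differential score (4908) had 1516, 2879, 3227 and 2749 to 7377, and 2145 and 2172 in single construct orders. Niraparib growth (18332) had 6443, 10488, 8509 and 9222 to 19448, and 11360 and 11980. With a T0 minimum of 10, EIF4G1-RCC1 was 0.03, NUP62-PSMB5 -0.18 and PARG-PLK1 0.11. With a score from the niraparib over reference ratio, BRCA1-PARP1 was -0.03, BRCA2-PARP1 -0.58, C4orf27-PARP1 -0.81, LIG3-PARP1 -0.29, NAMPT-PARP1 -0.14 and PALB2-PARP1 -0.31, and PARP1-POLB, CAD-RBM8A, COPS3-NOL6 and NOL6-UTP14A no longer passed.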

Other observations

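Tests of other splits and the choice of the gene pairs in the second paragraph were made after the result was seen; the further lists were written before any value was.

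Several lists outside the fixed ones rose under niraparib, but most did not when scaled to equal doublings, which lowers every depleted gene, and none passed with an estimated correlation (adjusted p of 0.354 to 0.557 for the 7 lists with camera calls). All 17 ribosome biogenesis genes rose (median log2 0.24, camera adjusted p = 0.00142), as did 10 of 11 mitochondrial translation genes (median 0.31, camera adjusted p = 0.00366), all 8 respiratory chain genes (median 0.29, camera adjusted p = 0.00759), 10 of 11 RNA polymerase and transcription factor genes (camera adjusted p = 0.0108) and all 6 one-carbon and serine metabolism genes (median 0.50, camera adjusted p = 0.034). All 7 genes of the COP9 signalosome and neddylation list fell (median -0.27, camera adjusted p = 0.00788) and all 8 of origin licensing and firing (median -0.13, camera adjusted p = 0.034). Scaled to the doublings of the reference arm, none of the 21 lists passed camera (adjusted p of 0.0931 to 0.905): ribosome biogenesis had 12 genes lower and 1 higher (median -0.16), mitochondrial translation 9 lower and 0 higher (median -0.27), and all 8 respiratory chain and all 11 RNA polymerase genes were lower (medians -0.21 and -0.23). One-carbon and serine metabolism kept 4 of 6 higher (median 0.26), and the COP9 and origin licensing genes all stayed lower. Unscaled, the other 14 had camera adjusted p of 0.0766 to 0.919. Adjusted over the list alone, the counts of the 7 were the same but for 11 RNA polymerase genes. The CCR4-NOT list had an upward test at a median of -0.02 and a mean of 0.01. In growth, the first 4 of these lists fell, with camera adjusted p of 0.0165 for ribosome biogenesis and mitochondrial translation and 0.0429 for the respiratory chain and RNA polymerases (adjusted p from 0.562 to 0.677 with an estimated correlation). Between the screens, 6 of the 21 lists passed (adjusted p = 0.454 with an estimated correlation).

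Gene pairs outside the fixed complexes also had like profiles, against a median r over all pairs of 0.0362 in the differential score. DNPH1-POLB reached 0.842, C4orf27-POLB 0.811 and LIG3-POLB 0.802. NAMPT-XRCC1 stood at 0.744 and LRRC45-XRCC1 at 0.746. In reference growth, the mitochondrial tRNA synthetases AARS2-LARS2 reached 0.789, the RAS regulators LZTR1-NF1 0.716 and SFXN1-SHMT2 0.7. In niraparib growth, MND1-PSMC3IP, partners in recombination, reached 0.834 and FAM96B (CIAO2B)-MMS19 of iron-sulfur cluster delivery 0.812.

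With the replicate pairs held, 8 splits of the libraries part all 4 pairs, which is too few for a share under 0.05, and in each case 1 of 8, the real split, gave as many calls. In edgeR fits of the 8 libraries of each comparison, the real split gave 443 genes in growth and 412 in response and the highest other split 0 in both, with up to 6 and 16 genes at an unadjusted p under 0.05. In limma, the real split gave 13158 pairs in reference growth, 4908 in the differential score and 18332 in niraparib growth, and the highest other split 2, 1 and 4. The 24 splits that part only 2 pairs gave 0 genes in both comparisons.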
